A study of Mus musculus with 12 samples.

How the data were processed

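Bulk RNA-seq counts of 12 mouse B-cell lymphomas were used, 1 file with 1 column per tumour. Per the labels, tumours came from spleens of iMycCα homozygous mice, cells were purified with B220 beads, libraries were made with a stranded total RNA kit that depletes ribosomal RNA, and paired reads were sequenced on a NovaSeq instrument. Per the submitters' processing notes the deposited values are estimated counts (expected counts) per Ensembl gene from a chain that names fastp 0.20.1, Salmon 1.5.2, DESeq2 and the mouse build mm10, without saying what each step did. The annotation release, the rounding and the choice of listed genes are not stated. All values were whole numbers with a different total in each library, so they were taken as rounded estimates that had not been scaled, and were used as they are. The files list 22119 genes, of which 22115 had a symbol, 16293 are protein-coding and 294 had no count in any library. Positions are from GENCODE's mm10 annotation. No file was a copy of another, and correlations between libraries over all 22119 listed genes, on log2(CPM + 1), were 0.916 to 0.988. The correlations in the report are over the 15103 tested genes, on edgeR's log CPM, and are lower.

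Total counts ranged from 22608829 to 44224844, a 1.96-fold range. Intervals for shares are 95% Wilson intervals. A gene without counts in a group was set against a floor of 3 counts over the group, and for 1 to 3 counts the ratio has an exact counting interval. Intervals and floors cover counting error only, since reads are not independent molecules. The counts do not separate strands, so antisense transcripts and reads shared between paralogs, such as immunoglobulin variable genes, cannot be excluded from a gene's value.

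Samples were grouped as the titles give them, 3 CD138-negative, 5 CD138-positive cmycM and 4 CD138-positive cmycP. Nothing in the labels says whether each library is a separate animal. The p-values therefore measure the spread between these samples, part of which may be technical. The first comparison set all 9 CD138-positive tumours against the 3 CD138-negative ones, and the second set cmycP against cmycM in a fit of all 3 groups. Genes were filtered with filterByExpr (minimum count 10), scaled by the trimmed mean of M values and tested with edgeR 4.0.16 quasi-likelihood F tests in R 4.3.3, at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the size of the log2 fold change divided by the square root of F. Single measures (Sdc1, Myc, variable gene shares) were tested with two-sided exact permutation tests on log2(CPM + 1) or percent. With 220 splits the smallest possible p is 0.00455 and with 126 it is 0.00794.

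Before the data were examined, 24 gene lists were fixed: flow panel, plasma cell, secretory pathway and unfolded protein response, mature B cell, germinal centre, B1 and marginal zone, memory and atypical B cell, B precursor, Myc targets, proliferation, glycolysis, NF-kB targets, immediate early, p53 targets, apoptosis regulators, interferon response, T cell, NK cell, macrophage and monocyte, plasmacytoid dendritic cell, neutrophil, erythroid, platelet and megakaryocyte, and stroma and endothelium. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. Lists share some members, such as Spn, Ighm and Sdc1. Ero1b was found as Ero1lb, and Ahsp, Aldoa and Mx1 were not found by symbol.

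The genes named in the text follow a rule also fixed before the data were examined. It takes Sdc1 and Myc, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM in the higher group, up to 3 called members with the smallest p of each list, and the immunoglobulin constant genes. Where fewer than 4 genes pass it takes the 5 smallest p-values. Immunoglobulin and T cell receptor segments, predicted genes and genes without a symbol were left out of it. Other genes that are named (Lyz2, Cd3e, Xist, Ddx3y, Gm26532, Vpreb1, Igll1, Fos, Fosb and Atf3) were chosen after their values were seen.

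Alternatives fixed beforehand were DESeq2 1.42.0, limma voom with quality weights, size factors by relative log expression, no filter, a filter of at least 1 CPM in 3 samples, robust estimation, a block for the replicate number, removal of immunoglobulin genes, a fit of 3 groups, each CD138-positive subset alone, the CD138-positive tumours alone, pseudocounts of 0.1 and 5, an estimated correlation, other shares of variable genes, and leaving out each library. Chosen after seeing the data were leaving out the 2 libraries that stood apart (for lists also with an estimated correlation), a term for Xist-expressing libraries (split at 50 CPM) and removal of abundant noncoding RNA. Replicate numbers do not pair the samples: of 10 pairs with the same number 2 had a correlation over 0.1, so no paired test was used.

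Group splits used 100 draws with a fixed seed. Chromosome-wide shifts are medians over 7867 genes with a mean of at least 10 CPM, relative to each gene's median over the 12 libraries. Values far from the rest of a group were sought with Dixon's test in groups of 4 to 9 libraries, and gene values under 1 CPM throughout a group were left out, a choice made after seeing that these are noise at the floor. The fits were tested on simulated data with 100 genes changed at each of 2 sizes. For the first comparison edgeR recovered 12 of 100 genes changed 2-fold and 49 of 100 changed 4-fold with 3 false calls, DESeq2 34 and 79 with 53 false calls, and voom 12 and 52 with 1 false call. For the second, edgeR recovered 13 and 57 with 2 false calls, DESeq2 31 and 73 with 43, and voom 12 and 56 with 1. camera recovered the 1 changed list of 24 without a false call in both. Simulated genes were drawn independently of each other, so this does not test camera on lists whose members move together. In the first comparison the estimated correlation of the NF-kB targets was 0.57. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.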

Results

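RNA was sequenced from 12 B-cell lymphomas that arose in the spleens of mice homozygous for iMycCα, a knock-in that places c-myc at the Cα constant gene of the immunoglobulin heavy-chain locus. Lymphoma cells had been collected with beads against B220, a surface protein of B cells, and all tumours were typed as positive for IgM and IgD. By flow cytometry 9 tumours carried CD138 (syndecan-1, a proteoglycan best known from plasma cells) and 3 did not. The sample titles divide the 9 CD138-positive tumours into 5 called cmycM and 4 called cmycP, and the labels do not explain these words. The same titles write cd138M for CD138-negative and cd138P for CD138-positive tumours, so M and P may mean minus and plus for cmyc too. Total counts lay between 22608829 and 31716199 in the CD138-negative libraries, between 25182366 and 33237437 in the cmycM libraries and between 28197735 and 44224844 in the cmycP libraries. Between 17346 and 19332 genes had at least 1 count in a library. Levels are given as CPM, counts scaled to a common library size after normalization by the trimmed mean of M values, and errors as the SD over tumours.

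Of the 9 CD138-positive libraries, 7 resembled each other, with correlations across the 15103 tested genes of 0.940 to 0.968 (genes are not independent replicates). The library labelled CD138+ cmycM replicate 5 and the library labelled CD138+ cmycP replicate 4 stood apart, at 0.892 to 0.930 with those 7 and 0.950 with each other. The 3 CD138-negative libraries were at 0.880 to 0.910 with each other. They were at 0.870 to 0.910 with the 2 that stood apart and at 0.819 to 0.873 with the 7. The 2 libraries that stood apart carried more RNA of macrophage genes than the other 7. Lyz2, the lysozyme of macrophages and granulocytes, was at 153 and 185 CPM in them, at 89.5 to 208 CPM in the 3 CD138-negative libraries and at 11.6 to 31.0 CPM in the other 7. Xist, the RNA of the inactive X chromosome, was at 134 to 1016 CPM in both of these libraries and in CD138-negative replicates 2 and 3. In the remaining 8 libraries it was at 0.0768 to 2.78 CPM and the Y-linked gene Ddx3y was expressed.

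The first comparison asks how CD138-positive lymphomas differ from CD138-negative ones. Sdc1, which encodes CD138 (ENSMUSG00000020592, chromosome 12, 8771323 to 8793715, mm10), averaged 41.9 ± 29.3 CPM in CD138-positive tumours (SD, n = 9) and 10.7 ± 6.27 CPM in CD138-negative tumours (n = 3). The ranges overlapped, at 2.57 to 106 and 4.13 to 16.6 CPM, and the lowest value of all came from the library labelled CD138+ cmycP replicate 4. The difference in mean log2(CPM + 1) was 1.63, with p = 0.0864 in a two-sided exact permutation test over 220 splits (Benjamini-Hochberg adjusted p = 0.148 over 4 such tests). edgeR gave a log2 fold change of 1.96 ± 0.79 (SE) with an adjusted p of 0.136. Without CD138-negative replicate 3 the difference was 1.15 and the exact p was 0.291. Without the library labelled CD138+ cmycP replicate 4 the difference was 2.05 and the exact p was 0.00606. Without both libraries that stood apart it was 2.08, with an exact p of 0.00833, the smallest that 120 splits can give. Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374) was at 221 ± 61.0 CPM (n = 9) in CD138-positive and 306 ± 62.9 CPM (n = 3) in CD138-negative tumours, a log2 fold change of -0.47 ± 0.23 that did not pass (edgeR adjusted p = 0.230) and was -0.27 (adjusted p = 0.590) without CD138-negative replicate 3. The exact permutation test gave a difference of -0.49 with p = 0.0773 and an adjusted p of 0.148. Counts per gene do not separate transcripts of the knock-in c-myc from those of the gene on chromosome 15. Myc values, here and below, may therefore include both.

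**Figure D1:**
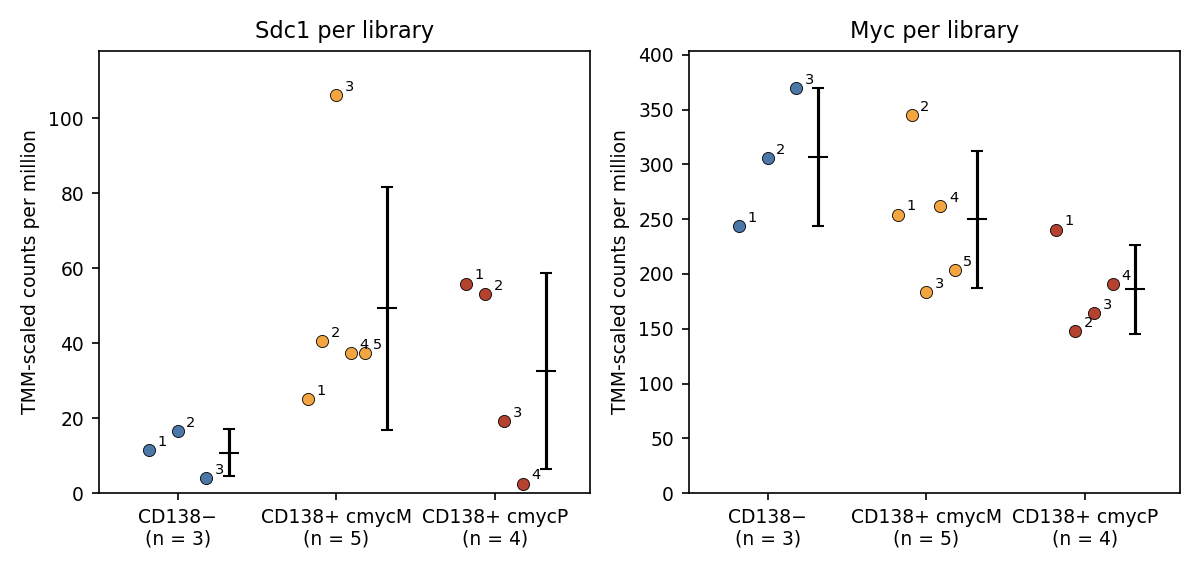
Sdc1 (left) and Myc (right) in each library, in CPM, by group; points are libraries and bars give the mean and SD. Sdc1 ranged from 2.57 to 106 CPM in the CD138-positive tumours and from 4.13 to 16.6 CPM in the CD138-negative ones.

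In CD138-positive tumours 11 of 15 NF-kB targets and 6 of 14 interferon response genes fell, and 3 of 11 B precursor genes rose. All 3 list calls were lost with an estimated correlation (adjusted p = 0.298, 0.298 and 0.364). Among 15 targets of NF-kB, a transcription factor family of immune activation, 11 fell, none rose and 4 did not pass, and adjusted over the list alone 13 fell. Nfkb1, which encodes an NF-kB subunit (ENSMUSG00000028163, chromosome 3, 135584655 to 135691547), was at 88.9 ± 41.2 CPM (n = 9) against 323 ± 87.6 CPM (n = 3), a log2 fold change of -1.86 ± 0.34 (adjusted p = 0.00421). Nfkb2, encoding another subunit, was at 13.3 ± 7.86 against 56.2 ± 26.6 CPM (log2 fold change -2.08 ± 0.42, adjusted p = 0.00817). Nfkbie, an inhibitor of NF-kB, fell by 2.22 ± 0.41 on the log2 scale (adjusted p = 0.00482). The list median was -2.22, and camera called the list lower than other genes (adjusted p = 4.08e-10), but adjusted p = 0.298 with an estimated correlation. Without the 2 libraries that stood apart 13 of the 15 fell. In the library labelled CD138+ cmycP replicate 4 the mean log2(CPM + 1) over the list was 4.64, above the 4.48 of CD138-negative replicate 2 and the 2.71 to 3.96 of the other 8 CD138-positive libraries. The T cell marker Cd3e was high in that library too, at 8.48 CPM, against 2.27 to 10.2 CPM in the CD138-negative libraries and 0.0584 to 1.04 CPM in the other 8.

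In the interferon response list 6 of 14 measured members fell, none rose and 8 did not pass, with 7 falling when adjusted over the list alone. Stat1, the transcription factor through which interferons signal (ENSMUSG00000026104, chromosome 1, 52119440 to 52161865), was at 99.8 ± 15.1 CPM (n = 9) in CD138-positive and 292 ± 76.9 CPM (n = 3) in CD138-negative tumours (log2 fold change -1.55 ± 0.17, adjusted p = 0.000185). Gbp2, an interferon-induced GTPase, was at 5.28 ± 5.37 against 110 ± 27.2 CPM (-4.38 ± 0.65, adjusted p = 0.00135), and Ifit1, an interferon-induced RNA-binding protein, fell by 2.62 ± 0.46 (adjusted p = 0.00375). The list median was -1.54 and camera gave an adjusted p of 2.64e-05, but adjusted p = 0.298 with an estimated correlation.

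Of 11 B precursor genes 3 rose, none fell and 8 did not pass, with the same counts adjusted over the list alone. Cd93, a surface marker of immature B cells (ENSMUSG00000027435, chromosome 2, 148436640 to 148443563), was at 186 ± 63.0 CPM (n = 9) in CD138-positive and 4.85 ± 3.46 CPM (n = 3) in CD138-negative tumours, a log2 fold change of 5.26 ± 0.71 (adjusted p = 0.000712). Vpreb3, a protein of precursor B cells, was at 131 ± 58.8 against 2.85 ± 3.33 CPM (5.51 ± 0.87, adjusted p = 0.00183). Il7r, the receptor for interleukin 7, was at 78.3 ± 47.1 against 8.22 ± 5.75 CPM (3.25 ± 0.64, adjusted p = 0.00681). The list median was 0.51 and camera called the list higher (adjusted p = 0.0110), but adjusted p = 0.364 with an estimated correlation. Without CD138-negative replicate 1 the camera call ended at an adjusted p of 0.0617. Vpreb1 and Igll1, which encode the surrogate light chain, had 3 and 2 counts in the CD138-negative libraries and 3481 and 3973 counts in the CD138-positive ones, and neither passed (adjusted p = 0.125 and 0.152). Both lie above the list median, which is therefore the same with these genes at their bounds.

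In the plasma cell list 6 of 22 measured genes fell, none rose and 16 did not pass, with 7 falling adjusted over the list alone. Creld2, a protein of the endoplasmic reticulum (ENSMUSG00000023272, chromosome 15, 88819646 to 88826683), was at 20.3 ± 4.81 CPM (n = 9) in the CD138-positive tumours and 94.4 ± 46.8 CPM (n = 3) in the CD138-negative ones (log2 fold change -2.21 ± 0.25, adjusted p = 0.000185). Ell2, an elongation factor that acts in the production of secreted immunoglobulin mRNA, fell by 2.81 ± 0.64 (adjusted p = 0.0143, 0.0891 without CD138-negative replicate 1). Ly6c2, a surface protein of plasma cells and monocytes, fell by 2.74 ± 0.59 (adjusted p = 0.0109), and without CD138-negative replicate 3 its value was -1.20 (adjusted p = 0.209). The list median was -0.71 and camera gave an adjusted p of 0.00928, but adjusted p = 0.298 with an estimated correlation, and 0.106 with the preset correlation without CD138-negative replicate 1. The secretory pathway and unfolded protein response list, 26 genes, had 1 that rose, 3 that fell and 22 that did not pass (2 and 5 adjusted over the list alone). Those that fell were the chaperones Pdia4 (-0.90 ± 0.21, adjusted p = 0.0168) and Hsp90b1 (-0.92 ± 0.25, adjusted p = 0.0334) and the stress sensor Ern1 (-1.39 ± 0.34, adjusted p = 0.0193). Each of these 3 calls ended when CD138-negative replicate 1 was left out, at adjusted p = 0.0973, 0.198 and 0.114, that of Pdia4 also without replicate 3 (0.0585), and that of Hsp90b1 in 6 of 12 fits that left out 1 library. The median was -0.05 and camera did not call the list (adjusted p = 0.968).

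Lists of other B-cell states were mixed. The mature B cell list had 25 genes, of which 4 rose, 1 fell and 20 did not pass (6 and 2 adjusted over the list alone), with a median of 0.12 and a camera adjusted p of 0.258. Ets1, a lymphocyte transcription factor, rose from 256 ± 52.8 CPM (n = 3) to 532 ± 80.8 CPM (n = 9), and Cr2, the complement receptor of mature B cells, rose by 6.44 ± 1.42 on the log2 scale (adjusted p = 0.00374 and 0.0122). Sell, the homing receptor L-selectin, fell from 256 ± 88.6 to 44.0 ± 39.6 CPM (adjusted p = 0.0123). The calls of Cr2 and Sell ended without CD138-negative replicate 1 (adjusted p = 0.0535) and replicate 3 (0.0537) respectively. Of 10 germinal centre genes 1 rose and 1 fell (3 and 1 adjusted over the list alone). These were Nuggc, a nuclear GTPase of germinal centre B cells, at 7.36 ± 2.08 (adjusted p = 0.0387, lost in 7 of 12 fits that left out 1 library), and the transcription factor Mef2b, at -5.11 ± 0.80 (adjusted p = 0.00180). Without the 2 libraries that stood apart 6 mature B cell genes rose and 3 fell, and 4 germinal centre genes rose and 2 fell. The germinal centre median was 0.07 and the mean 0.47, whereas camera's direction was down (adjusted p = 0.859).

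In the B1 and marginal zone list 4 of 11 genes fell and none rose (2 rose and 4 fell adjusted over the list alone). They included the inhibitory receptor Ctla4, at 3.33 ± 6.98 CPM (n = 9) against 103 ± 78.3 CPM (n = 3), and the transcriptional repressor Zbtb32, at 9.51 ± 11.2 against 100.8 ± 23.7 CPM (adjusted p = 0.0122 and 0.0252). Without CD138-negative replicate 1 these 2 adjusted p-values were 0.0582 and 0.0525, and without replicate 3 that of Zbtb32 was 0.0723. Ctla4 was at 21.83 CPM in cmycM replicate 2 and at 0.2005 to 2.755 CPM in the other CD138-positive libraries. The list median was -1.12, with a camera adjusted p of 0.0960. In the memory and atypical B cell list 2 of 8 fell and none rose (1 rose and 2 fell adjusted over the list alone), with a median of -1.22 and a camera adjusted p of 0.0960. Without the 2 libraries that stood apart 6 of 11 B1 and marginal zone genes and 3 of 8 memory and atypical B cell genes fell, and camera called both lists lower (adjusted p = 0.0146 and 0.000661), but adjusted p = 0.163 with an estimated correlation for each. Fcrl5, an Fc receptor-like protein of B cells, was at 0.690 ± 1.19 against 66.8 ± 72.2 CPM (adjusted p = 0.00456), and the integrin Itgax fell by 1.88 ± 0.55 (adjusted p = 0.0443, lost in 9 of 12 fits that left out 1 library). Among the CD138-negative libraries Fcrl5 ranged from 22.6 to 150 CPM, and without replicate 3 its edgeR adjusted p was 0.0322. In the flow panel list, the 7 genes of the markers used for typing, only Spn (CD43) passed, at 96.9 ± 30.6 against 211 ± 67.0 CPM (log2 fold change -1.12 ± 0.27, adjusted p = 0.0188, 0.130 without CD138-negative replicate 3 and 0.0504 without replicate 2), also adjusted over the list alone. That list's median was -0.03, its mean 0.04 and its camera adjusted p 0.949. Without the 2 libraries that stood apart 1 flow panel gene rose and 2 fell (camera adjusted p = 0.845).

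Of 10 apoptosis regulators 3 fell, none rose and 7 did not pass (5 fell adjusted over the list alone), with a median of -0.54 and a camera adjusted p of 0.0721. Without the 2 libraries that stood apart 4 of them fell and camera called the list lower (adjusted p = 0.0295), but adjusted p = 0.163 with an estimated correlation. Bcl2, which blocks cell death, was at 26.0 ± 28.6 CPM (n = 9) in CD138-positive and 147 ± 27.8 CPM (n = 3) in CD138-negative tumours (adjusted p = 0.0211). Single libraries had Bcl2 at 7.47 to 99.1 CPM in the former and 119 to 175 CPM in the latter group. The Bcl2 relatives Bcl2a1b and Mcl1 fell by 3.25 ± 0.68 and by 0.98 ± 0.26 (adjusted p = 0.00968 and 0.0288). The calls of Bcl2 and Mcl1 both ended without CD138-negative replicate 1 and without replicate 3, with adjusted p-values of up to 0.06697 and 0.103. Of 33 Myc targets 32 did not pass and 1 fell (also adjusted over the list alone), with a median of -0.02 and a camera adjusted p of 0.997, whereas without the 2 libraries that stood apart 4 rose and 2 fell (camera adjusted p = 0.568). That gene was Odc1, the rate-limiting enzyme of polyamine synthesis, at 278 ± 45.9 against 694 ± 178 CPM (log2 fold change -1.32 ± 0.18, adjusted p = 0.000762). In the glycolysis list 2 of 11 fell and none rose (also adjusted over the list alone), with a median of -0.15 and a camera adjusted p of 0.319. Hexokinase gene Hk2 fell by 1.46 ± 0.27 (adjusted p = 0.00473), and Pkm fell by 0.60 ± 0.17 (adjusted p = 0.0416), a call lost in 11 of 12 fits that left out 1 library. None of the 23 proliferation genes and none of the 11 p53 targets passed, nor did any adjusted over the list alone (medians -0.22 and -0.23, camera adjusted p = 0.347 and 0.707). Of 13 immediate early genes 1 rose and 2 fell (also adjusted over the list alone), with a median of -1.63 and a camera adjusted p of 0.232, and without the 2 libraries that stood apart 1 rose and 5 fell (camera adjusted p = 0.466). Dusp2, a phosphatase of MAP kinases, rose by 1.77 ± 0.34 (adjusted p = 0.00649). Egr1 and Nr4a3 passed at -2.44 ± 0.69 and -2.72 ± 0.80 (adjusted p = 0.0400 and 0.0453), but lost their calls in 7 and 9 of 12 fits that left out 1 library, and were at -0.35 and -0.24 without CD138-negative replicate 3 (adjusted p = 0.793 and 0.893).

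The number of T and NK cell genes that fell depended on the 2 libraries that stood apart. Without them 14 of 18 T cell genes fell and 1 rose (median -3.49, camera adjusted p = 1.90e-13), and 6 of 8 NK cell genes fell (median -3.09, 5.31e-06), but adjusted p = 0.163 and 0.189 with an estimated correlation. With all 12 libraries, in the T cell list camera gave an adjusted p of 0.00146 (down), but adjusted p = 0.704 with an estimated correlation. Of its 18 measured genes none then fell, 17 did not pass and 1 rose, Cd2, an adhesion molecule, at 163 ± 37.3 against 59.0 ± 38.3 CPM (adjusted p = 0.0338, lost in 4 of 12 fits that left out 1 library, at up to 0.0617 without CD138-negative replicate 2). No T cell gene passed adjusted over the list alone, and the list median was -1.73. Cd3e, a chain of the T cell receptor complex, was at 2.27 to 10.2 CPM in the CD138-negative libraries, at 8.48 CPM in the library labelled CD138+ cmycP replicate 4 and at 0.0584 to 1.04 CPM in the other 8. Cd2 did not follow Cd3e, at 123 to 236 CPM in single CD138-positive libraries and 16.5 to 91.0 CPM in CD138-negative ones. In the NK cell list 3 of 9 genes fell and none rose (also adjusted over the list alone), and camera gave an adjusted p of 0.00384 (median -1.45), but adjusted p = 0.666 with an estimated correlation. Gzmb, the protease granzyme B, was at 0.919 ± 0.757 against 27.3 ± 17.8 CPM (log2 fold change -4.88 ± 0.62, adjusted p = 0.000474). Eomes, a transcription factor of NK and T cells, fell by 3.63 ± 0.75, and Nkg7, a protein of cytotoxic granules, by 3.57 ± 0.93 (adjusted p = 0.00867 and 0.0281, the latter lost without CD138-negative replicate 2 or 3, at up to 0.107).

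None of the 14 macrophage and monocyte genes passed with all 12 libraries (median -0.60, camera adjusted p = 0.104). The mean log2(CPM + 1) over the list was 5.406 and 5.265 in the 2 libraries that stood apart, above the 3.66 to 4.98 of the CD138-negative libraries. Leaving out these 2 highest values, 9 of the 14 fell (median -2.18, camera adjusted p = 7.61e-09), but adjusted p = 0.163 with an estimated correlation. In the plasmacytoid dendritic cell list 1 of 7 rose and 1 fell (also adjusted over the list alone). These were Cox6a2, a muscle-type subunit of cytochrome c oxidase, at 7.13 ± 1.53, and Pacsin1, a membrane-shaping protein, at -4.19 ± 0.77 (adjusted p = 0.0109 and 0.00482, the latter 0.0515 without CD138-negative replicate 1). With a term for Xist-expressing libraries Cox6a2 was at 4.23 and its call ended (adjusted p = 0.0654). That list's median was -0.46 and its mean 0.36, with camera down at an adjusted p of 0.859. No gene passed, over all genes or adjusted over the list alone, among 13 neutrophil genes (median -1.27, camera adjusted p = 0.859), 13 erythroid genes (median -1.35, camera up, adjusted p = 0.859), 6 platelet and megakaryocyte genes (median -0.17, camera up, adjusted p = 0.709) and 9 stroma and endothelium genes (median 0.00, mean -0.79, camera down, adjusted p = 0.709). Haemoglobin transcripts took 3.72% of the counts in CD138-negative replicate 2, 0.0191% in CD138-negative replicate 3 and 0.281% to 0.761% in the other 10 libraries.

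**Figure D2:**
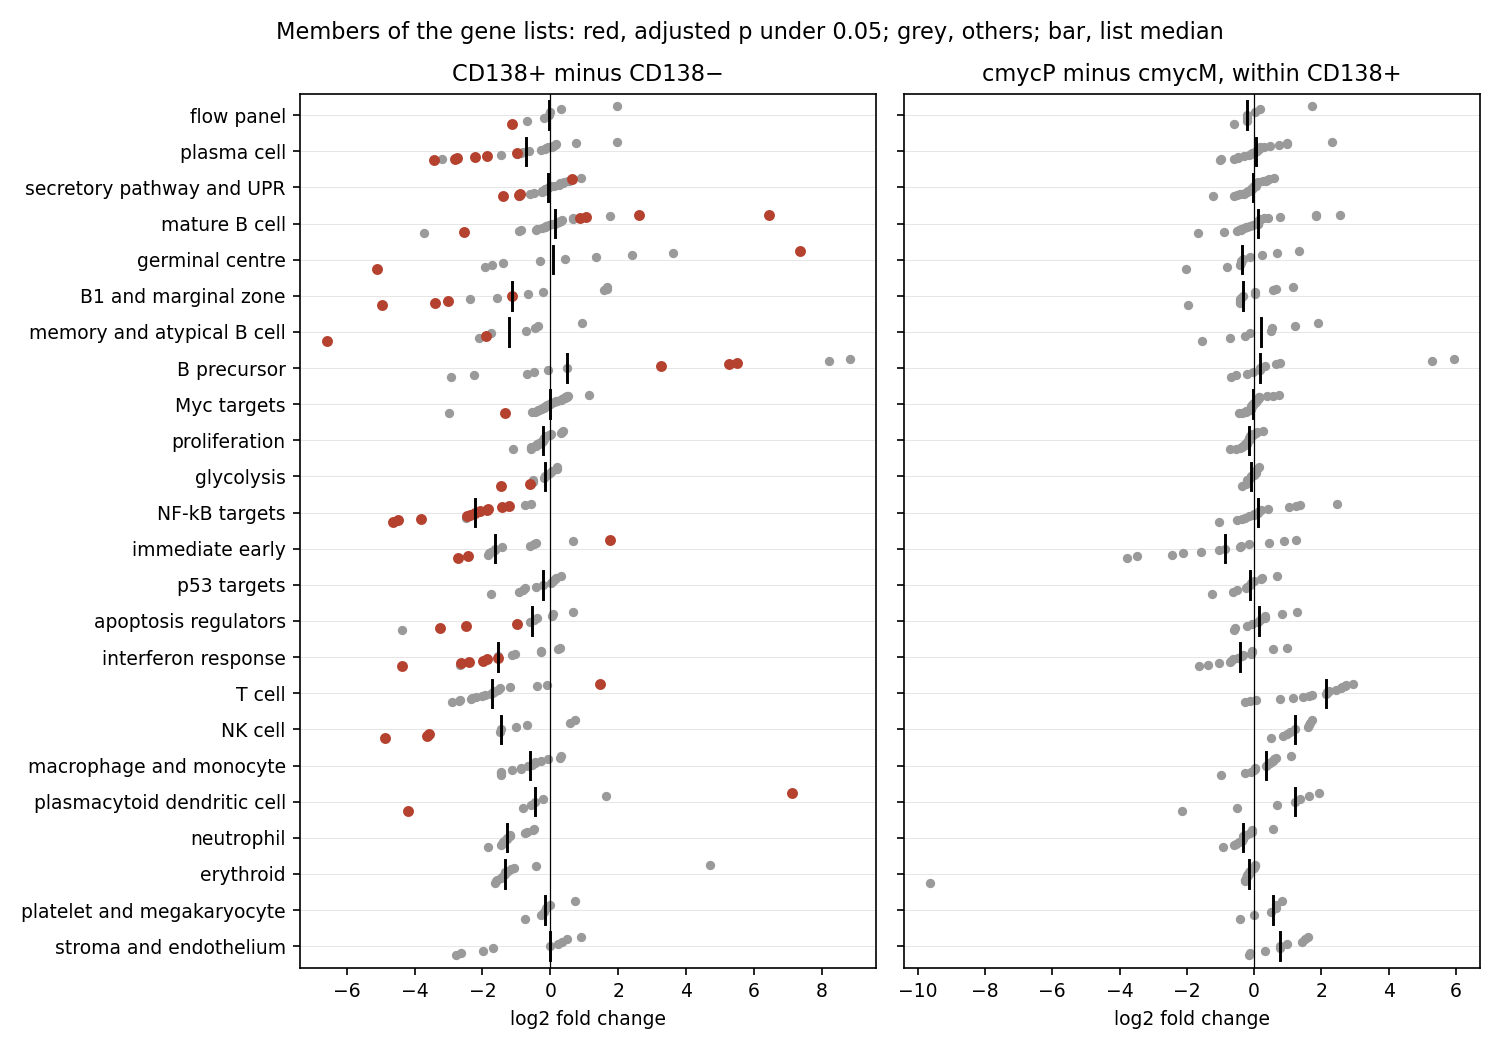
Log2 fold change of each measured member of the 24 gene lists, CD138-positive against CD138-negative tumours (left) and cmycP against cmycM (right); red points passed an adjusted p of 0.05, grey points did not, and the bar marks the list median. The NF-kB targets, with 11 members that passed, had a median of -2.22 in the left panel.

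Among the 8 largest rises was Ryr2, a calcium release channel known from heart muscle (ENSMUSG00000021313, chromosome 13, 11553102 to 12106945), at 69.9 ± 51.3 CPM (n = 9) in CD138-positive and 0.131 ± 0.124 CPM (n = 3) in CD138-negative tumours (log2 fold change 9.03 ± 1.93, adjusted p = 0.0109), and at 0.760 and 0.845 CPM in the 2 libraries that stood apart. With a term for Xist-expressing libraries its log2 fold change was 5.11 and its call ended (adjusted p = 0.0832). Nrxn1, a synaptic adhesion protein, was at 20.9 ± 12.8 against 0.0819 ± 0.142 CPM (log2 fold change 8.05 ± 1.28, adjusted p = 0.00194). Without CD138-negative replicate 3, the only CD138-negative library with counts of Nrxn1, the fit gave 12.39, which is not a measured ratio. No count of Greb1, Rtn4r or Gpr12 was seen in the CD138-negative libraries, so with counts pooled over each group they were at least 311-fold, 124-fold and 64.7-fold higher in CD138-positive tumours against a floor of 3 counts over the group (adjusted p = 0.0193, 0.00794 and 0.0305). Single CD138-positive libraries ranged from 0.432 to 29.8, from 0.263 to 8.33 and from 0 to 7.27 CPM for these genes. Shank2, a synaptic scaffold, had 2 counts in CD138-negative libraries (ratio 486, counting interval 135 to 4017) and the membrane protease Tmprss3 had 3 (ratio 431, 147 to 2090). Their adjusted p-values were 0.000429 and 0.0118. Tmprss3 was at 0.538 and 0.282 CPM in the 2 libraries that stood apart, Insm1 at 0 and 0.0626 CPM and the germinal centre gene Nuggc at 0.222 and 0.157 CPM. Insm1, a transcription factor of neuroendocrine cells, passed at 8.22 ± 2.41 (adjusted p = 0.0451) and lost its call in 10 of 12 fits that left out 1 library and with a term for Xist-expressing libraries (log2 fold change 4.16, adjusted p = 0.4935). That term ended 12 of the 56 calls of named genes, those of Ryr2, Insm1, Nuggc, Cox6a2, Egr1, Nr4a3, Hsp90b1, Itgax, Ly6c2, Mcl1, Pkm and Spn, at adjusted p-values of 0.0518 to 0.4935. With the term Pkm was at -0.67 ± 0.19, Hsp90b1 at -0.91 ± 0.27, Spn at -1.05 ± 0.33, Mcl1 at -0.84 ± 0.24 and Egr1 at -2.05 ± 0.99 (SE), 84.1% to 111% of their log2 fold changes without it. Ly6c2 (-2.12 ± 0.61), Nuggc (5.44 ± 1.62), Itgax (-1.24 ± 0.54), Nr4a3 (-1.69 ± 0.95), Cox6a2 (4.23 ± 1.29), Ryr2 (5.11 ± 1.66) and Insm1 (4.16 ± 2.99) kept 50.6% to 77.3%. A lost call alone does not show an effect of sex. In 3, 4 and 1 of the 12 fits that left out 1 library Greb1, Gpr12 and Tmprss3 lost theirs, with adjusted p-values of up to 0.0573, 0.0798 and 0.0516, each highest without CD138-negative replicate 1.

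In the other direction, the transcription factor Foxp2 (ENSMUSG00000029563, chromosome 6, 14901349 to 15441977) was at 12.9 ± 11.1 CPM (n = 3) in CD138-negative tumours and had 1 count in all 9 CD138-positive libraries (ratio 4135, counting interval 741 to 163444, adjusted p = 1.23e-05). Trpm5, a cation channel known from taste cells, was at 35.5 ± 34.6 against 0.0287 ± 0.0334 CPM (log2 fold change -10.12 ± 0.75, adjusted p = 1.28e-05). Etl4 was at 64.6 ± 50.7 against 0.0995 ± 0.103 CPM and Wipf3 at 21.3 ± 11.01 against 0.0305 ± 0.0619 CPM (adjusted p = 2.13e-05 and 5.13e-05). Sntg2, a syntrophin, had 3 counts in CD138-positive libraries (ratio 815, counting interval 278 to 3959, adjusted p = 2.26e-05). Cblc, a ubiquitin ligase, and Sycp2l had none and were at least 278-fold and 226-fold lower (adjusted p = 0.00526 and 0.00634). AF067061 averaged 58.2 ± 98.9 CPM in CD138-negative tumours (log2 fold change -9.50 ± 1.36, adjusted p = 0.000985), a value that became -3.71 without CD138-negative replicate 3 (adjusted p = 0.0571).

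In all, 1636 of 15103 tested genes (10.8%) differed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 603 higher and 1033 lower in CD138-positive tumours, and 914 of them by over 4-fold (216 higher, 698 lower). Of the 1636, 1463 are protein-coding, and 7 of 70 tested immunoglobulin and T cell receptor gene segments were among them. The count was 2735 with DESeq2, 959 and 306 with the cmycM or the cmycP tumours alone as the CD138-positive group, 1074 without CD138-negative replicate 1 and 2914 without the 2 libraries that stood apart. With limma voom and quality weights 1259 of 1582 calls (79.6%) were lower, against 63.1% here. Called genes were spread unevenly over chromosomes. On chromosome 16, which holds Rtn4r, 72 of 461 tested genes were higher (15.6%, adjusted p = 2.64e-22 by Fisher's exact test across genes, over both directions on 19 chromosomes), and on chromosome 15, which holds Creld2, Ly6c2, Il7r and Myc, 80 of 573 were lower (14.0%, adjusted p = 1.89e-08). In CD138-negative replicate 3 the median gene of chromosome 15 was 0.70 above its median over the 12 libraries on the log2 scale, and that of chromosome 16 was -0.40. These medians were 0.35 and -0.56 in replicate 2 and -0.09 and -0.19 in replicate 1. Genes of a chromosome moved together in single libraries, so Fisher's p-values across genes do not measure the spread between tumours. Of the 56 named genes called in this comparison, 54 had all 9 CD138-positive libraries on the called side of the CD138-negative mean and Gpr12 and Insm1 had 8 of 9, and 31 kept their call whichever library was left out. These genes were named because they passed in the same data, so the count of libraries on the called side is no independent support.

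No immunoglobulin constant gene passed between the 9 CD138-positive and 3 CD138-negative tumours. Ighm, the μ heavy chain, was at 2443 ± 333 CPM (n = 9) against 2435 ± 467 CPM (n = 3), and Ighd, the δ chain, at 33.3 ± 56.2 against 38.3 ± 20.7 CPM (edgeR adjusted p = 0.991 and 0.927). The Ighd mean rested on the library labelled CD138+ cmycP replicate 4, at 180.2 CPM, against 3.46 to 43.0 CPM in the other 8 CD138-positive libraries. Without the 2 libraries that stood apart Ighd passed, at a log2 fold change of -1.77 (adjusted p = 0.0116). Igkc, the κ light chain, was at 558 ± 144 against 580 ± 353 CPM (adjusted p = 0.940). The λ genes Iglc1, Iglc2 and Iglc3 were at 13.5 ± 20.7, 124 ± 136 and 44.6 ± 37.1 CPM against 53.9 ± 43.6, 193 ± 216 and 60.4 ± 35.5 CPM (adjusted p = 0.326, 0.729 and 0.815). Ighg1, Ighg2b and Igha averaged at most 2.51 CPM in either group (adjusted p = 0.552, 0.397 and 0.757). The highest heavy-chain variable (Ighv) gene held over 50% of the Ighv counts in 9 of 12 libraries, and it was a different gene in each. Its share was 65.5 ± 31.2% in CD138-positive (n = 9) and 77.9 ± 38.03% in CD138-negative tumours (n = 3), a difference of -12.3 percentage points (two-sided exact permutation p = 0.550, 220 splits). It was -1.39, -34.3 and -1.33 points without CD138-negative replicates 1, 2 and 3 (exact p = 0.927, 0.127 and 0.927), -7.73 without cmycM replicate 4 (0.733) and -5.11 without the library labelled CD138+ cmycP replicate 4 (0.758). In the library labelled CD138+ cmycP replicate 4 the highest gene, Ighv3-1, held 7.69% of 1040 Ighv counts (95% Wilson interval 6.22% to 9.47%), against 28.7% to 99.9% in the other 11.

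**Figure D3:**
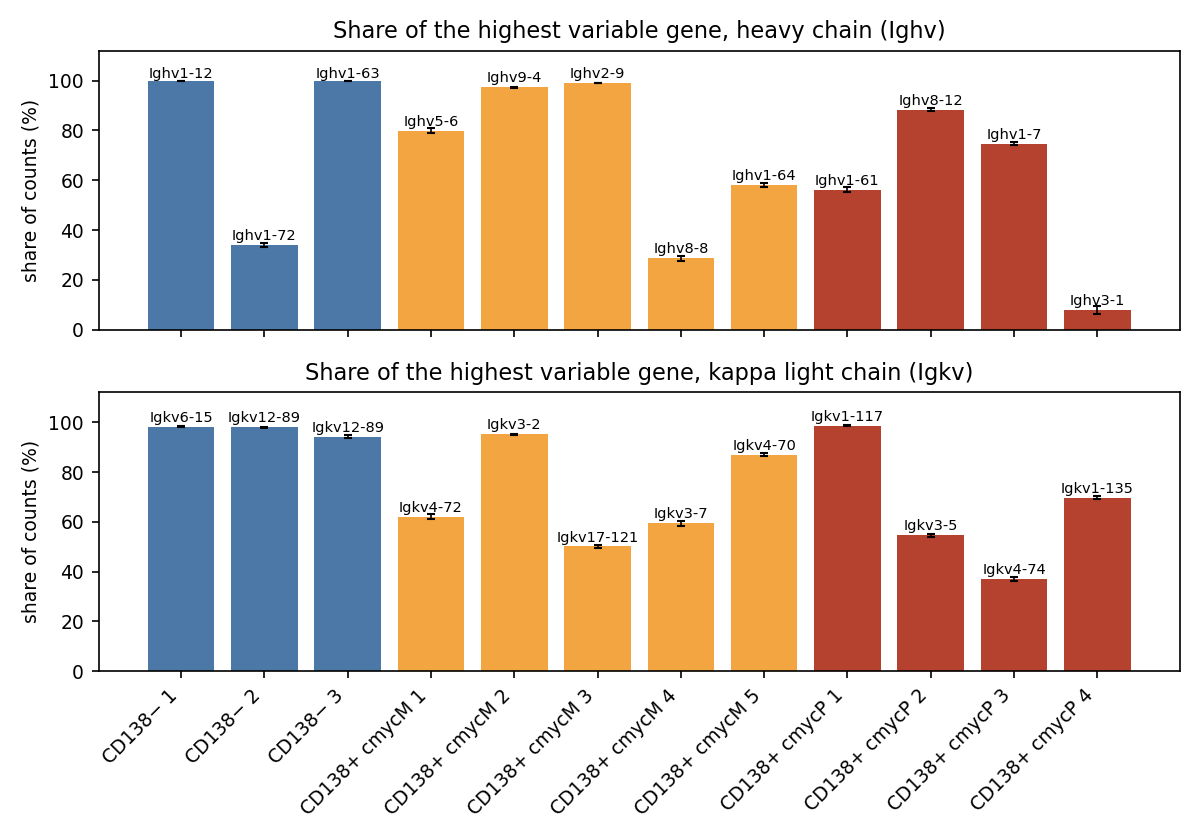
Share of the heavy-chain (top) and κ light-chain (bottom) variable gene counts held by the highest gene of each library, in percent, with 95% Wilson intervals. The library labelled CD138+ cmycP replicate 4 had 7.69% for Ighv and 69.8% for Igkv.

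The second comparison sets the 4 cmycP against the 5 cmycM tumours within the CD138-positive group. None of the 13 immediate early genes, which cells switch on within minutes of a stimulus, passed singly. camera called the list lower in cmycP (adjusted p = 1.43e-08), but adjusted p = 0.489 with an estimated correlation. Jun, a subunit of the transcription factor AP-1 (ENSMUSG00000052684, chromosome 4, 95049034 to 95052222), was at 7.27 ± 2.07 CPM (n = 4) in cmycP and 100 ± 56.3 CPM (n = 5) in cmycM tumours, a log2 fold change of -3.78 ± 0.69 (edgeR adjusted p = 0.972), and its highest cmycP value, 9.08 CPM, lay under its lowest cmycM value, 44.1 CPM. The log2 fold changes of Fos, Fosb and Atf3, which encode partners of Jun, were -2.11 ± 0.70, -2.43 ± 0.85 and -3.49 ± 1.22. Adjusted over the list alone 5 immediate early genes fell, and the list median was -0.86. Without the 2 libraries that stood apart the median was -1.64 (camera adjusted p = 2.29e-11), but adjusted p = 0.315 with an estimated correlation. Myc was at 186 ± 40.4 CPM (n = 4) in cmycP and 250 ± 62.8 CPM (n = 5) in cmycM tumours, a difference in mean log2(CPM + 1) of -0.41 (two-sided exact permutation p = 0.111, 126 splits, adjusted p = 0.148). Mean Myc RNA was thus not higher in cmycP tumours, and the labels do not say how cmyc was scored.

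edgeR called 0 of 15103 genes between cmycP and cmycM tumours (580 at an unadjusted p under 0.05, where 755 would be expected by chance), limma voom 0 (2972 unadjusted) and DESeq2 3 (907 unadjusted). The 3 genes, chosen after their values were seen, were Jun, Zfp821 and Gm26532, at DESeq2 log2 fold changes of -3.78, -0.98 and -2.23 (adjusted p = 1.23e-05, 0.00523 and 0.00135). Sell was at 73.4 ± 45.5 CPM (n = 4) against 20.6 ± 5.56 CPM (n = 5), Zfp966 at 16.3 ± 4.89 against 4.66 ± 1.79 CPM, Zfp821 at 5.02 ± 1.11 against 9.92 ± 1.05 CPM and Adck1 at 12.3 ± 1.93 against 5.79 ± 1.87 CPM, each with an edgeR adjusted p of 0.972. Sdc1 was at 32.7 ± 26.1 against 49.3 ± 32.3 CPM (difference in mean log2(CPM + 1) -1.03, two-sided exact permutation p = 0.349). Its edgeR log2 fold change of -0.59 (adjusted p = 0.980) was -0.21 without the library labelled CD138+ cmycP replicate 4, at 2.57 CPM against 19.1 to 55.9 CPM in the other 3, -0.0994 without cmycM replicate 3, -0.997 and -0.930 without cmycP replicates 1 and 2, and -0.30 without the 2 libraries that stood apart. Constant genes gave no call. Ighm was at 2248 ± 387 (n = 4) against 2599 ± 202 CPM (n = 5), Ighd at 54.5 ± 83.9 against 16.4 ± 15.5 CPM and Igkc at 442 ± 134 against 651 ± 62.2 CPM. Iglc1 was at 24.98 ± 28.0 against 4.34 ± 5.52 CPM, Iglc2 at 175 ± 192 against 83.0 ± 67.0 CPM and Iglc3 at 56.7 ± 49.1 against 34.9 ± 26.1 CPM. The ranges of Iglc2 overlapped, at 11.3 to 451 CPM in cmycP and 14.2 to 173 CPM in cmycM. Ighg1, Ighg2b and Igha averaged at most 2.90 CPM in either group.

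camera called 3 further lists between cmycP and cmycM. The interferon response list was lower in cmycP (14 genes, median -0.41, adjusted p = 0.00930), but adjusted p = 0.598 with an estimated correlation, and its call ended without cmycP replicate 1 (0.0533) or replicate 3 (0.0604). Its median was -0.87 without the 2 libraries that stood apart (camera adjusted p = 8.92e-05), but adjusted p = 0.430 with an estimated correlation. The T cell list was higher (18 genes, median 2.15, adjusted p = 0.00675), but adjusted p = 0.876 with an estimated correlation. The NK cell list was higher too (9 genes, median 1.22, adjusted p = 0.0212), but adjusted p = 0.876 with an estimated correlation. T and NK markers were highest in 1 cmycP library: Cd3e was at 8.48 CPM in the library labelled CD138+ cmycP replicate 4 and at 0.0584 to 0.430 CPM in the other 3. Without that library both lists turned to lower in cmycP, at adjusted p = 0.05799 for T cells and 0.917 for NK cells. Without both libraries that stood apart the T cell list was also lower (adjusted p = 0.319) and the NK cell list higher (0.3255), and neither was called. The NK call also ended without cmycM replicate 2, 3 or 4 or cmycP replicate 1, at 0.0533 to 0.0838.

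With all libraries the remaining 20 lists were not called between cmycP and cmycM and held no member that passed over all genes. Without the 2 libraries that stood apart camera called 3 of them, macrophage and monocyte genes higher (median 0.80, adjusted p = 3.88e-05) and neutrophil genes (-1.06, 0.0328) and NF-kB targets (-0.59, 0.0415) lower in cmycP, again with no member that passed, but adjusted p = 0.5003, 0.994 and 0.994 with an estimated correlation. Adjusted over the list alone, 1 mature B cell gene rose and 1 fell, 2 B precursor genes rose and no gene of the other 18 lists passed. Signs of median and test differed for mature B cell genes (median 0.11, camera down, adjusted p = 0.977) and NF-kB targets (0.13, down, adjusted p = 0.977). For the flow panel the median was -0.21 and the mean 0.10, with camera down (adjusted p = 0.613). For Myc targets the mean was 0.00 and the median -0.04, with camera down (adjusted p = 0.612). Medians of the other lists lay between -0.37 for germinal centre genes and 1.20 for plasmacytoid dendritic cell genes, whose camera adjusted p of 0.123 was the lowest of the lists not called.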

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

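The tests for a sex term, for mixed clones and for a variable gene missing from the files were chosen only after the result was seen, as was the second criterion for a wrong label.

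The first pattern is the 1636 genes called between CD138-positive and CD138-negative tumours. In 100 of the 220 possible splits of the same libraries the real one, counted as 1, called the most. This argues against chance for the genes without excluding it. The highest other split called 204 and set apart cmycM replicate 5, the library labelled CD138+ cmycP replicate 4 and CD138-negative replicate 2. All 3 express Xist, but another split with 3 Xist-expressing libraries called 6. They also had the highest mean log2(CPM + 1) over the macrophage and monocyte list (5.406, 5.265 and 4.98). RNA from macrophages is argued against as the whole source, since genes lower in CD138-positive tumours lay at a median position of at most 0.393 in the 2 libraries rich in macrophage RNA, where the macrophage markers lay at 2.685 and 2.266 (0 for the other CD138-positive and 1 for the CD138-negative libraries), and RNA from T and NK cells, since such genes lay at 0.626 in CD138-negative replicate 1, where T markers lay at 0.204 and NK markers at 0.130. Sex of the mouse is argued against as the whole cause, since 65.8% of the calls remained with a term for it. A difference between CD138-positive and CD138-negative lymphomas stays open as a hypothesis, and a part from other cells or sex may remain.

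The second pattern is the library labelled CD138+ cmycP replicate 4, with the lowest Sdc1 and no dominant Ighv gene. A mixture of many clones is argued against, since it had 1.91 Ighv counts per 100 Ighm counts, where the others had 9.81 to 27.7. A variable gene that the files do not count is a candidate explanation, since 1 Igkv gene held 69.8% of its Igkv counts (95% Wilson interval 69.1% to 70.5%), within the 37.0% to 98.7% of the others. Genes lower and higher in CD138-positive tumours lay in it at 0.470 and 0.442 of the way to the CD138-negative mean, between the other 8 CD138-positive libraries held out in turn (at most 0.147 and 0.351) and the CD138-negative ones (at least 0.561 and 0.649). A wrong label and a true CD138-positive tumour cannot be told apart, since these values lie under the bound of 0.5 set beforehand by less than the SD between held-out CD138-negative libraries (0.151 and 0.0776), and a criterion of over 2 SD below their mean, set after the result, was met by the higher genes (3.46 SD) and not by the lower genes (1.76 SD).

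The third pattern is expression shifted along whole chromosomes in 9 of 228 pairs of chromosome and library, the strongest being chromosome 15 in CD138-negative replicate 3 (median 0.70, interval 0.62 to 0.79) and chromosome 16 in replicate 2 (-0.56). GC content is argued against, since 8 of the 9 kept over 0.3 after a correction, the ninth keeping 0.292 of 0.329 (the 0.3 limit was chosen with shifts already seen under another gene filter, and the correction was changed to a median trend after a first run). A few genes or 1 region are argued against, since in 9 of 9 both parts of the chromosome and over 65% of its genes moved to the same side. For chromosome 15 in replicate 3 and chromosome 16 in replicates 2 and 3, RNA from T cells, NK cells and macrophages is argued against. Without genes that follow the markers of these cells the 3 shifts kept at least 85.2% of their size, although chromosome 3 in replicate 2 went from 0.33 to 0.22. Genes that follow other cell types were not removed. Replicate 2 had the highest erythroid and neutrophil scores (mean log2(CPM + 1) 8.95 and 5.22), so RNA from those cells stays open. The design gives no biological explanation and none was tested, and gain or loss of whole chromosomes may account for the pattern as a hypothesis.

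For the 6 lists called between CD138-positive and CD138-negative tumours chance cannot be excluded, since 73 of 100 splits gave as many and the highest other gave 14. Between cmycP and cmycM edgeR called 0 genes (580 at an unadjusted p under 0.05, DESeq2 3, voom 0). Any split reaches 0, so the count of 100 of 100 splits (1 gene for the highest other) decides nothing about the genes. For the 4 lists chance cannot be excluded, since 75 splits gave as many and the highest other gave 15.

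Single libraries lay far from the rest of their group in 41 of 279 tests of 102 measures, where chance gives about 1 in 20. Many of these measures move together, so they are not independent. Scores below are means of log2(CPM + 1) over a list.

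Against the other 8 CD138-positive libraries, the library labelled CD138+ cmycP replicate 4 was lower in glycolysis score (6.734, others 7.086 to 7.409), Sdc1 (2.567 CPM, others 19.15 to 106.2), Pkm (350.4) and Ighm (1704), and higher in the scores of apoptosis regulators (5.194) and T cells (3.968) and in Eomes (1.910), Nkg7 (5.917) and Pacsin1 (4.446). Against the other 3 cmycP libraries alone, it was lower in germinal centre score (1.238, others 2.395 to 2.542, with 1.033 in cmycM replicate 5) and Ryr2 (0.8453). Within cmycP it was higher in the scores of memory and atypical B cells (3.633), macrophages and monocytes (5.265) and plasmacytoid dendritic cells (2.676), and in Ly6c2 (33.69), Fcrl5 (2.348), Nfkbie (35.88), Nfkb2 (21.98) and Nr4a3 (1.691).

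Against the other 4 cmycM libraries, cmycM replicate 5 was higher in NK cell score (1.602), macrophage and monocyte score (5.406), Fcrl5 (3.165 CPM) and Nkg7 (1.329 CPM) and lower in Ryr2 (0.7596 CPM). Against the other 8 CD138-positive libraries it was lower in Cd93 (31.62 CPM, others 168.1 to 249.6). Of the CD138-positive group, cmycM replicate 2 had the lowest proliferation score (5.148, others 6.168 to 7.086), Pdia4 (105.4 CPM) and Hsp90b1 (303.8 CPM) and the highest Ctla4 (21.83 CPM), cmycM replicate 3 the highest Il7r (198.2 CPM), cmycP replicate 2 the highest B precursor score (3.569) and cmycP replicate 3 the highest stroma and endothelium score (2.138). Within cmycM alone, Igha was highest in replicate 2 (4.725 CPM) and the mature B cell score lowest in replicate 3 (6.256). Within cmycP alone, replicate 1 had the highest Ighg1 (1.633 CPM) and the lowest Zfp966 (8.937 CPM).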

How the results depend on the processing

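Leaving out the 2 libraries that stood apart (also with an estimated correlation), the Xist term and the removal of noncoding RNA were chosen after seeing the data. The number of genes called between CD138-positive and CD138-negative tumours, 1636, was 2735 with DESeq2, 959 and 306 with cmycM or cmycP tumours alone (fewer samples), 2914 without the 2 libraries apart, and 1074 to 2272 when 1 library was left out. In the other 10 settings it was 1245 to 1782. Of the 1636 genes, 893, 1085 and 898 stayed called without CD138-negative replicates 1, 2 and 3. Leaving out 1 CD138-positive library kept 1174 to 1597 of them. With limma voom 1139 stayed called and with the replicate block 1141. All of these kept their direction. The 6 called lists were 0 with an estimated correlation, 10 without the 2 libraries apart (gaining B1 and marginal zone, memory and atypical B cell, apoptosis and macrophage), 0 without them with an estimated correlation, and 4 to 10 with 1 library left out. Between cmycP and cmycM the 0 genes were 3 with DESeq2, and the 4 lists were 0 with an estimated correlation, with or without the 2 libraries apart, and 3 to 8 with 1 library left out. The Sdc1 difference in mean log2(CPM + 1) of 1.63 was 1.15 to 2.05 with 1 library left out. Its exact p was then 0.00606 to 0.291, lowest without the library labelled CD138+ cmycP replicate 4. The fitted log2 fold change of Sdc1, another measure, was 1.95 with DESeq2, where it passed (adjusted p = 0.0363). With edgeR it was 1.96 (adjusted p = 0.136), and 2.25 with a replicate block (0.152). Except where fewer samples were used, the cause was not tested.

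No called gene turned in the settings tallied for single genes, which leave out limma voom. Constant genes, none of which was called in the comparisons as reported, turned as follows. The value of Ighm log2 fold change, CD138+ vs CD138- was -0.00728 with DESeq2, -0.00927 with relative log expression, -0.0106 with 3 groups, -0.11 with cmycP alone, -0.0769 with the Xist term and -0.0897 to 0.16 with 1 library left out. Ighd was at 0.51 with cmycP alone and -1.33 to 0.34 with 1 left out, Igkc at 0.16 with cmycM alone and -0.30 to 0.57, Iglc2 at -1.21 to 0.80 and Iglc3 at -0.68 to 0.16. Between cmycP and cmycM, Ighg2b was at 0.30 with the Xist term and -1.81 to 0.44 with 1 left out, Ighd at -0.36 to 2.45 and Igha at -0.66 to 0.89.

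With a block for the replicate number the value of Igha log2 fold change, cmycP vs cmycM was -0.00539, and 1539 genes and 9 lists were called in the first comparison.

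These tallies, too, leave out limma voom. For 67 named genes of the first comparison 1477 of 1661 values kept their direction and side of the threshold, 163 lost the call and 4 gained it, 3 of Sdc1 and 1 of Ighd, which was at -1.77 without the 2 libraries apart. For 16 of the second 346 of 359 kept both. Depth limits genes with 3 or fewer counts in a group. In the simulated data, with 100 genes changed at each of 2 sizes, most 2-fold changes were missed. The first comparison called 1636 genes, and the adjusted threshold is looser where more genes change, so the simulated recovery cannot be carried over to it.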

Other observations

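Igkv12-89 was the highest κ gene in CD138-negative replicates 2 and 3, at 98.0% and 94.3% of the Igkv counts, and 11 different κ genes led in the 12 libraries. The highest κ gene held 68.2 ± 21.2% of the Igkv counts in CD138-positive (n = 9) and 96.8 ± 2.18% in CD138-negative tumours (n = 3), values that were not tested. It held over 50% in 11 of 12 libraries.

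Besides chromosome 16, 4 of 19 chromosomes differed from the rest in the share of genes higher in CD138-positive tumours. It was larger on chromosome 10, with 58 of 716 (8.10%, adjusted p = 3.11e-06 by Fisher's exact test across genes), and smaller on chromosome 3 with 12 of 793 (1.51%, adjusted p = 0.000521), chromosome 17 with 15 of 764 (1.96%, 0.0171) and chromosome 7 with 29 of 1174 (2.47%, 0.0254). Genes of a chromosome are not independent, so these p-values do not measure the spread between tumours. The SD of chromosome medians was 0.22 and 0.27 in CD138-negative replicates 2 and 3, 0.17 in the library labelled CD138+ cmycP replicate 4 and 0.041 to 0.11 in the other 9.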
